A study of Homo sapiens with 12 samples.

How the data were processed

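Expression was measured by RNA-seq of poly(A)-enriched RNA from manually picked colonies of 2 human embryonic stem cell lines, in 4 groups of 3 libraries: primed H9, naive H9, primed RUES2 and naive RUES2. The design text calls the 3 libraries of a group biological replicates without saying how the cultures were separated, so p-values measure the spread between these libraries. Per the submitters' processing notes, bcl2fastq 2.17.1.14 and TopHat2 2.1.1 and the genome build hg19 were used. The program that computed the expression values and its gene annotation are not given in the sources used here. The authors deposited 1 table per library with FPKM per gene, its confidence bounds and a status, per the file headers. The design text speaks of RPKM while the headers name FPKM, and the values were treated as FPKM. Each table listed 25278 entries for 23615 gene symbols. Entries on haplotype or unplaced contigs (1303) and 23 copies on 1 sex chromosome of genes of the other were left out, which removed 25 symbols. For 287 symbols with several loci the locus with the highest mean was kept. The 23590 symbols left had 2 values with a status other than OK. No libraries held identical values, and 0 columns could not be assigned to a sample. Coordinates are 1-based and on hg19 as deposited. The reference in hand, of another build, served only for transcript lengths by symbol.

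The tables hold no read counts. With the confidence bounds read as 2 standard deviations of a counting error, they imply the fewest fragments in primed H9 replicate 1 and the most in naive H9 replicate 3, and a median of 47.8 to 112 fragments for genes of 1 to 2 FPKM. Of values under 60 implied fragments, 40.3% to 43.5% lay within 0.05 of a whole number, so whole reads were not recovered and no count test was run. Depth relative to the mean over libraries, from 15825 genes, ran from 0.651 to 1.54, a ratio of 2.37 between the deepest and the shallowest library. FPKM sums ran from 754205 to 986125. Short RNAs, which poly(A) libraries measure poorly, took 35.1% to 50.1% of the sum, and MIR4461 alone took 16.8% to 33.1%. The strandedness of the libraries is not given in the sources used here, so values of overlapping or antisense genes are uncertain, as are those of genes with near-identical copies such as POU5F1, NANOG, TDGF1, KRT8, HSPA8, UQCRH, COX7B, COX7C, CD24 and the HLA genes.

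Genes with at least 1 FPKM in at least 3 libraries (14429) were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), two-sided, in 1 linear model with a mean per group for all 12 libraries and an empirical Bayes variance trend. The comparisons were naive against primed in each line, the mean of both, their difference, and RUES2 against H9 in each state. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes were called at an adjusted p under 0.05. The agreement of the lines was described by correlation across genes and by overlaps beside those of independent lists, since the state comparisons share no library. Replicate numbers are shared between groups in the labels, and a fit with the number as a block was run as an alternative. Tables and plots were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

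Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, beside camera with an estimated correlation and fry, adjusted over 25 lists of at least 5 measured genes. Members under the filter of 1 FPKM did not enter. Naive libraries count towards that filter, so it can favour members that rise there. With the estimated correlation 0 lists were called in any comparison. Fry called 14 lists in H9, 13 in libraries labelled RUES2 and 0 for the difference, and its mixed test, for change in either direction, called 24, 25 and 16. The lists were core, naive and primed pluripotency, targets of MEK and ERK, of WNT and beta-catenin, of LIF and STAT3, of hypoxia and of p53, lysosome, mTOR pathway, glycolysis, nuclear oxidative phosphorylation, DNA methylation and demethylation, cholesterol synthesis, ATF4 and unfolded protein response, proliferation and heat shock proteins, and markers of neural ectoderm, mesendoderm, definitive endoderm, primitive endoderm, trophectoderm, amnion, the 8-cell stage, fibroblasts and neural crest. The median, mean and test direction of a list differed only in lists that were not called.

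Genes are named by a rule with 4 parts. A fixed set of 29 pluripotency, signalling and mTOR-related genes is given in both lines. The 8 genes with the highest and the 8 with the lowest mean fold change come from those called in the same direction in both lines, with a group mean of at least 5 FPKM and no overlap between states (3048 genes). Each list gives up to 4 called members with the largest mean change. The difference between lines and each line difference give the 5 highest and 5 lowest called genes with a group mean of at least 5 FPKM. Some genes that this rule selects are not reported here. Sex-linked marker genes, mitochondrially encoded genes, replication-dependent histone genes and short RNAs were left out of the ranked parts. The samples' groups, the tests, the lists, this rule and most alternatives were chosen before the data were examined. Other members of lists that are named (VENTX, CDH2, CRABP2, VIM, SPRY2, SPRED2, CCND1, EPHA2, GAA, RRAGD, WIPI1, LHX1, SOX17, UQCRFS1, CTSD, ENO1, TBX6, S100A4, NKD1, TNFRSF19, RNF43 and PMVK) were chosen after their values were seen.

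The alternatives were other pseudocounts, filters, scalings between libraries, variance models, library weights, thresholds, fits on 6 libraries, the replicate block and leaving out each library. Those added after the data were examined were scaling by sums without short RNAs, a filter on implied fragments, leaving out both primed replicates 2, which resemble each other, and leaving out the libraries labelled naive RUES2. The limma steps were tested on 1 simulated data set per comparison for the 14429 genes, with known changes in 200 of them. Far more genes were called between the real states (6392 in H9), so the recovery need not carry over. In the H9 comparison 50.7% of 1.5-fold, 77.6% of 2-fold and 93.9% of 4-fold changes were recovered, and 2.63% of calls were false. For the difference between lines 23.9%, 67.2% and 92.4% were recovered, with 2.4% of calls false. False calls made up 2.87% for the mean state effect, 5.73% in RUES2, 6.37% between the naive and 7.55% between the primed groups. The last 3 lay above the 5% aimed at, with 9, 10 and 12 false calls in 1 draw each. A check of line identity used genotype-dependent genes. Mouse reads from feeder cells were not analysed here.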

Results

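Poly(A) RNA was sequenced from 2 established human embryonic stem cell lines, H9 and RUES2, each grown in a primed and in a naive state, to compare gene expression between the states. There were 4 groups of 3 biological replicates (n = 3 libraries per group, 12 in all). Primed cells (passages 31 to 35 for H9 and 30 to 33 for RUES2) grew on mitotically inactivated mouse embryonic fibroblasts with 4 ng/mL bFGF. Naive cells (passages 27 to 31 and 24 to 26) grew in medium with 5 mM glucose, 18 µg/mL insulin, 20 ng/mL LIF, 1 µM of the MEK inhibitor PD0325901 and 3 µM of the GSK3 inhibitor CHIR99021. The labels of these libraries name no mTOR inhibitor, although the study concerns a brief inhibition of mTOR. Values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library). Between 12681 and 13593 genes per library reached 1 FPKM. Values below are mean FPKM ± SD over the 3 libraries of a group. Fold changes are differences of mean log2(FPKM + 1), which understate the change of genes of low level, and adjusted p-values are from limma.

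Libraries of 1 group resembled each other more than libraries of different states. The median correlation across genes was 0.931 within primed H9, 0.958 within naive H9, 0.943 within primed RUES2 and 0.950 within libraries labelled naive RUES2. It was 0.886 between the states of H9, 0.878 between the states of RUES2, 0.933 between the primed groups and 0.936 between the naive groups. Genes are not independent replicates, and these correlations are descriptions. In a check of line identity with genotype-dependent genes, 3 of the 12 libraries, none of them labelled H9, did not match the other libraries of their line label. That check sees only lines that differ in these genes, so a match does not settle which line a library is. The state comparison in H9 contrasts libraries labelled H9 alone. In all other comparisons directions are those of the libraries as labelled.

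The comparison within H9 asked how the transcriptome of the naive state differs from that of the primed state in this line. Transcripts of POU5F1 and SOX2 were lower in naive H9. POU5F1 (OCT4; chromosome 6, 31132114 to 31138451 of hg19) fell from 909.8 ± 104 to 436 ± 17.7 FPKM (log2 fold change -1.05, adjusted p = 0.000138). SOX2 (chromosome 3, 181429712 to 181432223) fell from 101 ± 7.06 to 58.6 ± 1.37 (-0.78, 0.00192). TERF1, which binds telomeres, fell from 176 ± 26 to 28.7 ± 1.07, and TDGF1, a co-receptor of NODAL, from 248.5 ± 72.1 to 72.1 ± 4.08. NANOG (chromosome 12, 7941995 to 7948655) measured 77.7 ± 24.8 and 43.9 ± 3.19 and did not pass the test (adjusted p = 0.0958). Nor did ZFP42 (REX1; 69.6 ± 1.95 and 64.5 ± 3.95, adjusted p = 0.467). Of 18 measured core pluripotency genes, 8 fell, 2 rose and the others did not pass, with the same numbers when adjusted over the list alone. The genes that rose were NODAL (log2 fold change 2.15, adjusted p = 0.0413) and GDF3 (1.67, 0.0188), both ligands of the TGF-beta family. The NODAL call ended without any 1 of the naive H9 libraries (adjusted p 0.0734 to 0.105), any 1 of the libraries labelled naive RUES2 (0.0518 to 0.0532) or primed RUES2 replicate 1 (0.0549). The GDF3 call ended without primed H9 replicate 2 (0.061) or 3 (0.0613) or naive H9 replicate 2 (0.0594). By limma's camera test the list was lower than other genes (adjusted p = 0.0179, and adjusted p = 0.563 with an estimated correlation). That call ended without primed H9 replicate 1 (0.0663) or 3 (0.0603).

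Several naive-state markers rose in H9 and most primed-state markers fell. DNMT3L, a cofactor of the de novo DNA methyltransferases (chromosome 21, 45666222 to 45682099), rose from 0.375 ± 0.445 to 13.7 ± 3.77 FPKM (3.42, adjusted p = 8.38e-05). KHDC3L, a component of the oocyte subcortical complex, rose from 0.0824 ± 0.107 to 9.48 ± 2.5. The growth factor gene FGF4 rose from 2.13 ± 1.75 to 12.7 ± 2.47 and the transcription factor gene TFAP2C from 4.88 ± 3.54 to 18.2 ± 0.758. KLF2 rose from 0.126 ± 0.0936 to 2.74 ± 0.427, KLF5 from 0.732 ± 0.336 to 2.36 ± 0.786 and the surface antigen gene SUSD2 from 1.96 ± 0.513 to 4.05 ± 0.378. KLF4 (1.31 ± 0.955 and 1.48 ± 0.431), DPPA3 (2.08 ± 0.586 and 3.1 ± 0.594) and DPPA5 (0.793 ± 1.1 and 0.34 ± 0.481) did not pass. KLF17, TFCP2L1 and ESRRB were below the expression filter, with group means of at most 0.104, 0.922 and 0.0612 FPKM over all 4 groups. Of 27 listed naive pluripotency genes 19 passed the filter, which can favour genes that rise in naive libraries. Of these 19, 12 rose and 1, VENTX, fell (12 and 2 adjusted over the list alone). The VENTX call ended without any 1 H9 library other than primed replicate 2, at 0.0549 to 0.11. By camera the naive list was higher (adjusted p = 0.000558, and adjusted p = 0.561 with an estimated correlation). Among primed markers, the de novo DNA methyltransferase gene DNMT3B (chromosome 20, 31350191 to 31397162) fell from 317 ± 60.1 to 77.7 ± 5.17 (adjusted p = 5.11e-06). The homeobox gene OTX2 fell from 53.6 ± 14.6 to 8.95 ± 1.31 and the surface antigen gene THY1 from 112 ± 27 to 21.2 ± 2.49. The neuroligin gene NLGN4X fell from 39.1 ± 8.99 to 1.46 ± 0.126 and the receptor phosphatase gene PTPRZ1 from 56.1 ± 18.9 to 7.94 ± 1.21. B3GAT1 fell from 8.7 ± 2.47 to 0.588 ± 0.217 and ZIC2 from 64.4 ± 10 to 24.6 ± 2.06. The surface antigen gene CD24 also fell (-1.38, 4.51e-06), with a level that is uncertain because near-identical copies share its reads. SFRP2 did not pass (113 ± 69.6 and 74.5 ± 11.3, adjusted p = 0.375). Of 23 measured primed pluripotency genes, 15 fell and 3 rose (16 and 3 adjusted over the list alone), the risers being CDH2, CRABP2 and VIM. Camera placed the list lower (adjusted p = 0.000524, and adjusted p = 0.254 with an estimated correlation).

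Target genes of the pathways addressed by the naive medium moved in H9 to different extents. All 18 measured WNT and beta-catenin target genes rose, also when adjusted over the list alone. SP5, a transcription factor gene induced by WNT (chromosome 2, 171571857 to 171574498), rose from 4.22 ± 4.04 to 94.8 ± 14.4 FPKM (4.56, adjusted p = 0.000119). The feedback inhibitor AXIN2 (chromosome 17, 63524683 to 63557740) rose from 7.49 ± 1.57 to 46.5 ± 1.78 (2.50, 2.33e-06). DKK1, which encodes a secreted WNT antagonist, rose from 0.972 ± 0.603 to 24.8 ± 5.6, MIXL1 from 8.87 ± 8.5 to 55.6 ± 4.5 and LEF1 from 0.784 ± 0.955 to 12.5 ± 4.26. Camera placed this list higher (adjusted p = 9.73e-12, and adjusted p = 0.251 with an estimated correlation). Of 20 MEK and ERK target genes, 9 fell and 4 rose (9 and 4 adjusted over the list alone). The list was not called (camera, adjusted p = 0.242). The ERK phosphatase gene DUSP6 fell from 35.9 ± 34 to 1.28 ± 0.313 (-3.64, 0.000704) and the immediate early gene EGR1 from 7.42 ± 5.69 to 0.206 ± 0.0617. ETV1 fell from 11.7 ± 2.58 to 2.02 ± 0.493 and SPRY4 from 22.1 ± 9.86 to 5.27 ± 1.01, while SPRY2, SPRED2, CCND1 and EPHA2 rose. Of 13 measured LIF and STAT3 target genes 5 rose (7 adjusted over the list alone). Among them were GBX2 (1.07 ± 1.01 to 32 ± 3.73), IL6ST, which encodes the shared LIF receptor subunit gp130 (1.69 ± 0.351 to 14 ± 4.58), and SOCS3 (4.84 ± 1.49 to 11.4 ± 2.61, adjusted p = 0.0129, ended without naive H9 replicate 3 at 0.0509). JUNB measured 2.44 ± 1.9 and 2.92 ± 0.247 and did not pass (adjusted p = 0.401). Camera placed the LIF and STAT3 list higher (adjusted p = 0.0187, and adjusted p = 0.497 with an estimated correlation). This call ended without primed H9 replicate 1 (0.0574), without both primed replicates 2 (0.0581) and with a filter of 5 FPKM (0.134), over a range of 0.00468 to 0.134.

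Some genes of oxidative phosphorylation and of the lysosome rose in naive H9, and a few glycolysis genes fell. Of 39 nuclear oxidative phosphorylation genes, 17 rose and 1 fell, also when adjusted over the list alone. UQCRH rose from 545 ± 9.13 to 873 ± 16.3, COX7B from 279.6 ± 5.19 to 466 ± 32 and NDUFB3 from 45.5 ± 1.06 to 61.8 ± 3.07, and COX7C fell from 1489 ± 162 to 836 ± 20.5. Of 37 measured lysosome genes, 19 rose and 4 fell (20 and 4 adjusted over the list alone). Examples were the protease gene CTSL1 (17.7 ± 1.08 to 52.6 ± 10.7) and UVRAG (2.67 ± 0.75 to 4.34 ± 0.273). GPNMB did not pass (0.307 ± 0.0616 and 0.544 ± 0.125). Among the lysosome genes that fell were GAA (-1.23), RRAGD (-1.15) and WIPI1 (-0.90). The WIPI1 call ended without naive H9 replicate 1 at 0.0609 or 2 at 0.123 or primed H9 replicate 1 at 0.0505 or 3 at 0.119. Both lists were placed higher by camera (adjusted p = 0.000558 for each, and adjusted p = 0.561 with an estimated correlation). Of 23 glycolysis genes 5 fell and 0 rose (4 and 0 adjusted over the list alone), led by the aldolase gene ALDOC (38.7 ± 0.996 to 11 ± 0.409). Camera placed the list lower (adjusted p = 0.0388, and adjusted p = 0.563 with an estimated correlation). This call ended without primed H9 replicate 1 (0.114) or 3 (0.108). ENO2 fell (-0.68, adjusted p = 0.0153, ended without primed H9 replicate 3 at 0.0562 or naive H9 replicate 1 at 0.0509). SLC16A3 (16.6 ± 6.69 and 9.32 ± 1.87) and PFKFB4 (6.87 ± 2.5 and 4.75 ± 0.428) did not pass. MTOR itself measured 20.3 ± 2.56 and 19.2 ± 0.868 and did not pass (adjusted p = 0.607). TFE3, a transcription factor of lysosomal genes, measured 21.3 ± 1.58 and 24.1 ± 3.01 and did not pass either (0.24). Of 23 measured mTOR pathway members, 5 rose and 4 fell (the same adjusted over the list alone; camera, adjusted p = 0.794). The mTORC1 inhibitor gene DDIT4 fell from 76.7 ± 8.98 to 16.9 ± 3.12 and RICTOR from 3.44 ± 0.228 to 1.96 ± 0.206. GATSL3 did not pass (3.22 ± 0.654 and 2.88 ± 0.512) and AKT1S1 rose (0.62, adjusted p = 0.019, ended without naive H9 replicate 3 at 0.0616).

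Other metabolic, stress and growth lists were not called in H9. Of 13 measured DNA methylation and demethylation genes 3 rose and 2 fell (camera, adjusted p = 0.682). DNMT3L and UHRF1 (20.1 ± 10.9 to 44.9 ± 2.48) were among the risers, while TET1 did not pass (adjusted p = 0.0669). Of 23 cholesterol synthesis genes 2 rose, NSDHL (24.1 ± 11.9 to 49.2 ± 2.88) and EBP (55 ± 18.7 to 102 ± 8.03), and 0 fell (adjusted p = 0.279). MVK (7.4 ± 4.61 and 10.7 ± 1.08) did not pass. Of 21 ATF4 and unfolded protein response genes 5 rose and 7 fell (adjusted p = 0.849). The cystine transporter gene SLC7A11 rose from 4.29 ± 0.366 to 22.9 ± 3.3, while CHAC1 fell from 19.4 ± 4.21 to 4.9 ± 0.421 and VLDLR from 15.2 ± 7 to 2.54 ± 0.229. Of 17 measured hypoxia target genes 1 rose, LOX (0.684 ± 0.391 to 3.21 ± 0.33), and 3 fell, ADM (32.9 ± 0.289 to 11 ± 3.63), VEGFA (15.1 ± 5.65 to 4.67 ± 0.437) and EGLN3 (13.5 ± 4.73 to 4.44 ± 0.516), at adjusted p = 0.279 for the list. Of 18 p53 target genes 5 rose and 2 fell (5 and 1 adjusted over the list alone; adjusted p = 0.207). BTG2 rose from 3.23 ± 1 to 12.1 ± 1.53 and CDKN1A rose (1.47, adjusted p = 0.0157, ended without primed H9 replicate 1 at 0.0582 or naive H9 replicate 3 at 0.0628). RRM2B fell (-0.84, 0.0193, ended without primed H9 replicate 3 at 0.0719 or naive H9 replicate 3 at 0.0509) and ZMAT3 did not pass. Of 22 proliferation genes 5 rose and 3 fell (4 and 3 adjusted over the list alone; adjusted p = 0.522). TYMS rose from 38.9 ± 14.4 to 78.3 ± 5.13, RRM2 rose (0.69), and MCM3 (-0.51) and TOP2A (-0.38) fell. Of 12 heat shock protein genes 3 rose and 2 fell (adjusted p = 0.239). BAG3 rose from 5.68 ± 1.22 to 13.5 ± 3.91 and HSPH1 from 48 ± 12.6 to 77.1 ± 3.2. DNAJA1 also rose (0.55, adjusted p = 0.0208, ended without naive H9 replicate 3 at 0.0717), while HSPA8 did not pass (adjusted p = 0.11). For the methylation, cholesterol, ATF4, hypoxia and heat shock lists the counts were the same when adjusted over the list alone.

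Several markers of early lineages and of fibroblasts rose in naive H9. Of 14 measured mesendoderm markers 9 rose and 1 fell (the same adjusted over the list alone; camera, adjusted p = 0.00749, and adjusted p = 0.439 with an estimated correlation). They included T (brachyury, 1.09 ± 1.04 to 13.4 ± 0.977), HAND1 (1.64 ± 2.76 to 41.9 ± 29.3) and FGF8 (10.1 ± 7.75 to 39.7 ± 6.62). The list call ended with a filter of 5 FPKM (0.0726, range 0.000603 to 0.0726). The marker that fell was LHX1 (-0.79, ended without any 1 of the naive libraries or primed RUES2 replicate 1 or 2, at 0.0523 to 0.107). Of 16 listed neural ectoderm markers 9 were measured, and 5 of these rose, or 6 adjusted over the list alone (camera, adjusted p = 0.00714, and adjusted p = 0.439 with an estimated correlation). Among them were OLIG3 (0.492 ± 0.157 to 20.3 ± 1.18), MAP2 (1.59 ± 1.73 to 9.04 ± 1.93) and TUBB3 (87 ± 20.6 to 174 ± 9.06). FABP7 did not pass (adjusted p = 0.0688). Of 12 primitive endoderm markers 7 rose and 1 fell (the same adjusted over the list alone; adjusted p = 0.0177, and adjusted p = 0.563 with an estimated correlation, ended without primed H9 replicate 1 at 0.0574). Risers included GATA4 (to 8.97 ± 3.28, adjusted p = 0.000112), NID2 (1.48 ± 0.824 to 15.7 ± 11.5), FLRT3 (1.56 ± 0.622 to 7.79 ± 1.93) and the collagen gene COL4A2 (24 ± 1.31 to 59.8 ± 21.2). SOX17 fell (-0.69, ended without any 1 naive H9 library, primed H9 replicate 1 or 2 or primed RUES2 replicate 1, at 0.0501 to 0.115). Of 12 listed amnion markers 7 were measured. Markers of low primed level pass the filter mainly where they rise. Of the 7 measured 5 rose, also adjusted over the list alone (camera, adjusted p = 0.00749, and adjusted p = 0.439 with an estimated correlation). They included BMP4 (5.02 ± 0.89 to 37.7 ± 17.7), ID2 (20.7 ± 9.59 to 60.7 ± 6.16), POSTN (0.692 ± 0.195 to 4.49 ± 1.11) and CDH10 (0.163 ± 0.166 to 1.62 ± 0.158). Of 18 measured fibroblast markers 11 rose and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 0.00247, and adjusted p = 0.563 with an estimated correlation). COL3A1, LUM and DCN (0.134 ± 0.0914 to 7.01 ± 1.57) were among the risers, and the marker that fell was THY1. The lists of trophectoderm (3 higher and 1 lower of 8, 4 and 1 adjusted over the list alone; adjusted p = 0.207), neural crest (6 and 3 of 11, 6 and 4; 0.345) and definitive endoderm markers (2 and 2 of 9, the same; 0.88) were not called. In them CDX2 (0.461 ± 0.798 to 9.65 ± 2), KRT8 (150.2 ± 27.9 to 424 ± 88.7) and MSX1 (1.07 ± 1.82 to 15 ± 9.09) rose. SNAI2 (0.739 ± 0.901 to 15.4 ± 9.32), TWIST1 (0.858 ± 1.07 to 3.35 ± 0.337) and GATA6 (1.56 ± 0.701 to 6.25 ± 2.54) rose. KRT7 (3.77 ± 0.322 to 0.187 ± 0.0245), FOXD3 (7.87 ± 0.513 to 0.175 ± 0.113) and HHEX (1.24 ± 0.466 to 0.155 ± 0.0465) fell, and NR2F2 and TTR did not pass. Of 14 8-cell stage markers 2 were measured, KHDC1L (0.157 ± 0.204 to 2.64 ± 0.977) and SLC34A2 (0.347 ± 0.0576 to 1.77 ± 0.227). Both rose and the list was too short to test.

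Over all 14429 genes tested in H9, limma called 6392 at an adjusted p under 0.05, 2943 higher and 3449 lower in naive cells. Of these 1687 differed by at least 1 on the log2 scale. Without the 3 libraries labelled naive RUES2 in the fit, 5962 genes were called. Rescaling each library to a common sum moved the share of higher genes among the calls from 46% to 28.1%. It moved the median log2 fold change of all genes from -0.01 to -0.123. Of 25 lists tested by camera 13 were called, 10 higher and 3 lower, and with an estimated correlation 0 were called.

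**Figure D1:**
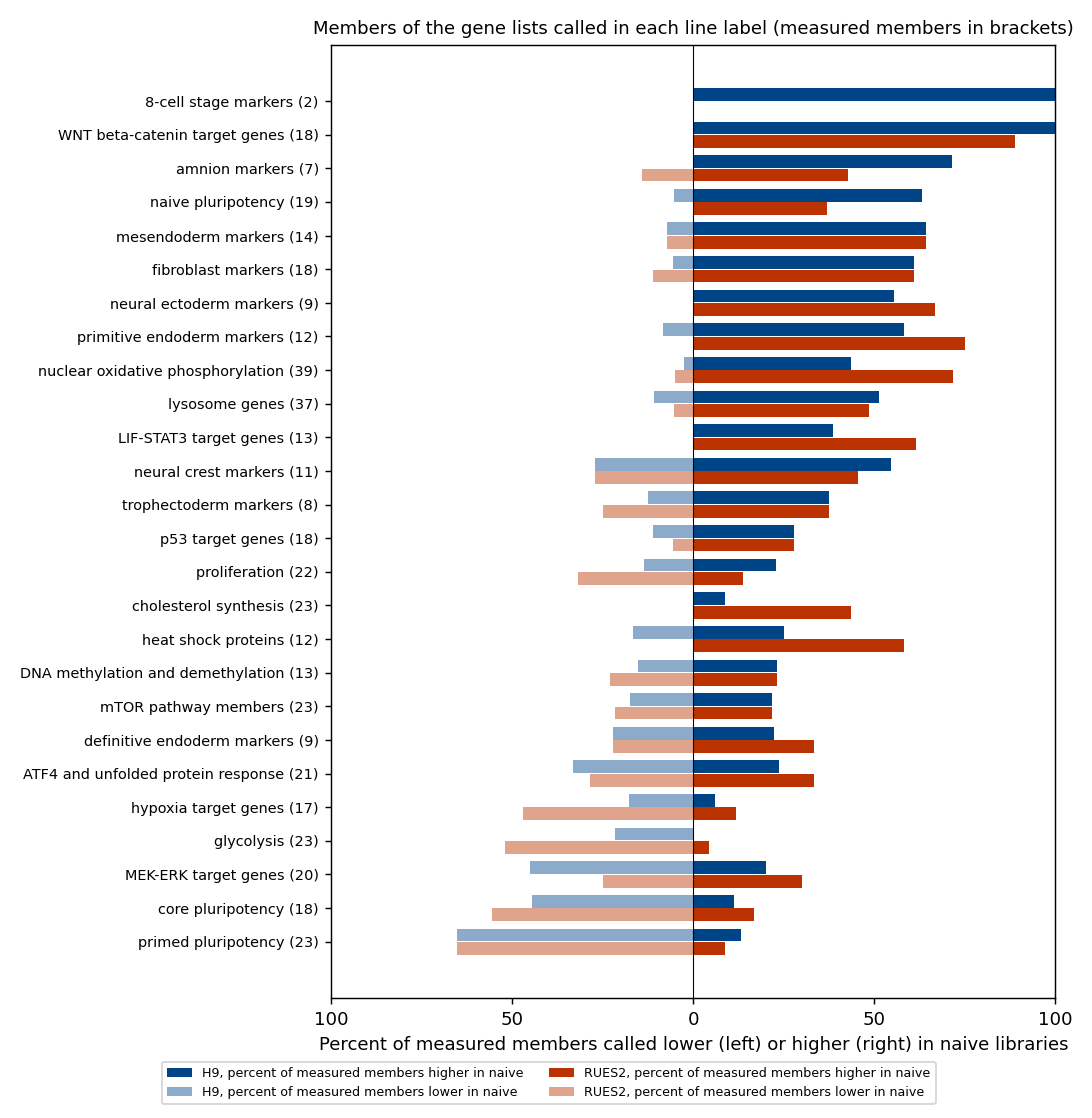
Percent of the measured members of each gene list called higher (bars to the right) or lower (paler bars to the left) in naive than in primed libraries, for H9 (blue) and for libraries labelled RUES2 (red), with the number of measured members in brackets. All 18 measured WNT and beta-catenin target genes were higher in naive H9 and 16 in libraries labelled RUES2.

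The same question was put to the libraries labelled RUES2, a comparison that the 3 libraries that did not match their line label enter. Here too POU5F1 fell (779 ± 108 to 527 ± 64.9 FPKM, -0.56, adjusted p = 0.00526) and SOX2 fell (109 ± 25.6 to 38.9 ± 4.75, -1.44, 4e-05). TERF1 (197 ± 10.3 to 30.2 ± 4.1), TDGF1 (287.5 ± 90.4 to 100.4 ± 29.6) and ZFP42 (71.1 ± 10 to 35.4 ± 4.63) fell as well. NANOG rose from 50.8 ± 15.7 to 299.9 ± 140 (2.49, 0.000249). Of the 18 core genes 10 fell and 3 rose (11 and 3 adjusted over the list alone; camera, adjusted p = 0.0133, and adjusted p = 0.598 with an estimated correlation). The list call ended when libraries were rescaled to a common sum (0.0994, range 0.00416 to 0.0994). The other risers, NODAL (2.61, 0.0169) and GDF3 (1.56, 0.0236), lost their calls without primed RUES2 replicate 2 (0.0592 and 0.0875) or naive RUES2 replicate 1 (0.0574 and 0.0824). Of 27 listed naive genes 19 were measured, and of these 7 rose and 0 fell, also adjusted over the list alone (camera, adjusted p = 0.0165, and adjusted p = 0.668 with an estimated correlation). This call ended without naive RUES2 replicate 1 (0.0538) and with a filter of 5 FPKM (0.111), over a range of 0.000565 to 0.111. DNMT3L rose from 0.837 ± 0.469 to 44 ± 26.8, FGF4 from 2.82 ± 1.01 to 14.5 ± 4.26, KLF2 from 0.135 ± 0.0732 to 2.36 ± 0.952 and SUSD2 from 0.698 ± 0.134 to 4.18 ± 1.36. KLF4 (3.04 ± 0.81 and 4.63 ± 1.42), KLF5 (2.58 ± 0.412 and 4.18 ± 1.29) and TFAP2C (10.6 ± 2.58 and 18.3 ± 2.19) did not pass, nor did DPPA3 (4.76 ± 2.77 and 6.38 ± 4.41), DPPA5 (1.75 ± 1.15 and 1.25 ± 0.832) and KHDC3L (0.0682 ± 0.118 and 0.199 ± 0.0929).

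Most primed markers fell in the libraries labelled naive RUES2 and most WNT targets rose. DNMT3B fell from 405 ± 42.4 to 61.3 ± 8.67, OTX2 from 63.8 ± 20.4 to 16 ± 4.51, and THY1 from 73 ± 30 to 11.1 ± 4.95. NLGN4X fell from 28.6 ± 3.5 to 1.05 ± 0.344, PTPRZ1 from 40.9 ± 1.71 to 7.38 ± 1.58, B3GAT1 from 7.26 ± 1.82 to 0.417 ± 0.193, and CD24 by fit (-1.78, adjusted p = 1.06e-06). Of 23 primed genes 15 were lower and 2 higher (16 and 3 adjusted over the list alone; camera, adjusted p = 9.83e-05, and adjusted p = 0.304 with an estimated correlation). ZIC2 (39.1 ± 21.2 and 30.7 ± 4.53) and SFRP2 (79.7 ± 22.4 and 56.1 ± 7.38) did not pass. Of 18 WNT target genes 16 rose and 0 fell, also adjusted over the list alone (adjusted p = 1.55e-07, and adjusted p = 0.304 with an estimated correlation). SP5 rose from 3.29 ± 1.85 to 67.6 ± 12.6, DKK1 from 1.95 ± 0.75 to 25.5 ± 7.74, and MIXL1 from 6.55 ± 6.26 to 71.4 ± 17.6. LEF1 rose from 0.937 ± 0.197 to 7.54 ± 1.48 and AXIN2 from 10.9 ± 0.961 to 25.3 ± 5.5. Of 20 MEK and ERK targets 6 rose and 5 fell (6 and 7 adjusted over the list alone; adjusted p = 0.838). EGR1 (6.93 ± 2.42 to 0.0967 ± 0.0636) and ETV1 (8.79 ± 0.77 to 1.87 ± 0.253) fell. DUSP6 fell (-1.94, adjusted p = 0.0192, ended without primed RUES2 replicate 3 at 0.0692 or naive RUES2 replicate 2 at 0.0648). SPRY4 did not pass (adjusted p = 0.0931). Of 13 LIF and STAT3 targets 8 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.00106, and adjusted p = 0.304 with an estimated correlation). Among them were GBX2 (0.702 ± 0.392 to 14.6 ± 2.72), IL6ST (1.91 ± 0.0563 to 12.4 ± 1.86), SOCS3 (4.12 ± 1.83 to 15.2 ± 5.18) and JUNB (1.65 ± 0.388 to 7.56 ± 1.06).

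Many oxidative phosphorylation genes and some lysosome genes rose and some glycolysis genes fell in the libraries labelled naive RUES2. Of 39 oxidative phosphorylation genes 28 rose and 2 fell, also adjusted over the list alone (camera, adjusted p = 1.64e-06, and adjusted p = 0.579 with an estimated correlation). COX7B rose from 282 ± 14.8 to 647 ± 46.8, UQCRH from 599 ± 69.2 to 949 ± 65.2 and NDUFB3 from 45.1 ± 7.09 to 78.9 ± 2.86. COX7C (1585 ± 108 to 961 ± 37.1) and UQCRFS1 (-0.33) fell. Of 37 lysosome genes 18 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.00284, and adjusted p = 0.598 with an estimated correlation). They included CTSL1 (25.1 ± 1.92 to 51 ± 17.9), UVRAG (2.23 ± 0.478 to 5.2 ± 0.339) and GPNMB (0.406 ± 0.129 to 2.58 ± 0.896). CTSF and CTSD fell, the latter (-0.28) with a call that ended without naive RUES2 replicate 1 or 2 or any 1 primed RUES2 library (0.0536 to 0.107). Of 23 glycolysis genes 12 fell and 1 rose (13 and 1 adjusted over the list alone; adjusted p = 0.00723, and adjusted p = 0.579 with an estimated correlation). ALDOC fell from 38.4 ± 4.77 to a mean of 11.9, ENO2 from 67.5 ± 17.4 to 28.7 ± 4.25 and the lactate transporter gene SLC16A3 from 28.1 ± 11.5 to 9.1 ± 3.8. The rise of ENO1 (0.33) ended without any 1 naive RUES2 library or primed RUES2 replicate 2 or 3 (0.0619 to 0.102). The fall of PFKFB4 (-1.32, adjusted p = 0.039) was kept only when the library left out was primed H9 replicate 2 or 3 or primed RUES2 replicate 3 (0.0509 to 0.0931 without any other 1), and without primed RUES2 replicate 2 it measured -0.67 (0.0718). Of 23 cholesterol synthesis genes 10 rose and 0 fell (3 and 0 adjusted over the list alone; adjusted p = 0.00238, and adjusted p = 0.669 with an estimated correlation). NSDHL rose from 20.9 ± 5.97 to 50.5 ± 2.9. EBP did not pass (48.7 ± 6.62 and 66.4 ± 2.02). MVK rose (0.87, 0.0415). Its call ended without any 1 of the naive H9 or naive RUES2 libraries, primed RUES2 replicate 1 or 2 or primed H9 replicate 1 (0.0508 to 0.147). MTOR did not pass (19.1 ± 2.04 and 16.3 ± 0.914, adjusted p = 0.108) and TFE3 fell from 23 ± 2.33 to 16 ± 1.42 (-0.50, 0.00384). Of 23 mTOR pathway members 5 rose and 5 fell, also adjusted over the list alone (adjusted p = 0.936). DDIT4 (176.5 ± 98.1 to 36.4 ± 3.85), RICTOR (3.15 ± 0.122 to 2.07 ± 0.106) and GATSL3 (4.28 ± 0.0714 to 2.04 ± 0.78) fell and AKT1S1 rose (21 ± 2.34 to 38.6 ± 4.61).

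The stress, growth and DNA methylation lists were not called in the libraries labelled RUES2. Of 13 DNA methylation genes 3 rose and 3 fell, also adjusted over the list alone (camera, adjusted p = 0.838). TET1 fell from 16 ± 3.54 to 8.55 ± 1.32 and UHRF1 did not pass (17.8 ± 3.18 and 31.8 ± 2.9). Of 21 ATF4 and unfolded protein response genes 7 rose and 6 fell (8 and 6 adjusted over the list alone; adjusted p = 0.838). SLC7A11 rose from 7.7 ± 0.318 to 12.2 ± 2.61, and CHAC1 fell from 36.1 ± 10.4 to a mean of 14.6 and VLDLR from 17 ± 2.99 to 7.45 ± 1.71. Of 17 hypoxia targets 2 rose and 8 fell (2 and 9 adjusted over the list alone; adjusted p = 0.114). Among them were LOX (1.08 ± 0.39 to 8.15 ± 6.33), ADM (45.2 ± 7.47 to 16.1 ± 5.24), VEGFA (25.9 ± 6.14 to 10.6 ± 0.746) and EGLN3 (26.4 ± 8.1 to 6.32 ± 2.27). Of 18 p53 targets 5 rose and 1 fell (5 and 0 adjusted over the list alone; adjusted p = 0.0835). CDKN1A rose from 8.8 ± 4.45 to 44.2 ± 11.5, BTG2 from 4.3 ± 0.482 to 16.1 ± 1.73 and ZMAT3 by 0.86 on the log2 scale to 4.68 ± 0.823. RRM2B fell (-0.69, adjusted p = 0.0429), a call kept only when the library left out was primed H9 replicate 2 or 3 or primed RUES2 replicate 2 (0.054 to 0.149 without any other 1). Of 22 proliferation genes 3 rose and 7 fell, also adjusted over the list alone (adjusted p = 0.189). TYMS rose from 32 ± 3.46 to 58.8 ± 3.99, while MCM3 fell from 164 ± 9.31 to 94.1 ± 3.12 and TOP2A from 81.4 ± 4.69 to 61.4 ± 1.6. The rise of RRM2 (0.64, 0.019) ended without primed RUES2 replicate 1 (0.0732) or naive RUES2 replicate 2 (0.0513). Of 12 heat shock genes 7 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.122). HSPH1 rose from 47.9 ± 7.08 to 75 ± 3.6. The rises of BAG3 (0.63, 0.0293) and HSPA8 (0.59, 0.0238) each ended without primed RUES2 replicate 1 (0.0672 and 0.0904), primed RUES2 replicate 2 (0.0978 and 0.0574), naive RUES2 replicate 1 (0.0827 and 0.0642) or a further library, naive RUES2 replicate 3 for BAG3 (0.0891) and replicate 2 for HSPA8 (0.0844). That of DNAJA1 (0.46, 0.0413) was kept only when the library left out was primed H9 replicate 2 or 3 (0.0513 to 0.126 without any other 1).

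Several lineage and fibroblast markers rose in the libraries labelled naive RUES2 as well. Of 14 mesendoderm markers 9 rose and 1 fell, also adjusted over the list alone (camera, adjusted p = 0.0344, and adjusted p = 0.579 with an estimated correlation). T rose from 1.07 ± 0.652 to 15.2 ± 4.96 and FGF8 from 5.5 ± 1.93 to 32.6 ± 4.13, and TBX6 fell (-0.87). The list call ended without naive RUES2 replicate 1 (0.0547), primed H9 replicate 3 (0.0566) or primed RUES2 replicate 2 (0.0892). HAND1 rose (2.82, adjusted p = 0.0138, ended without primed RUES2 replicate 2 at 0.0526). Of 16 listed neural ectoderm markers 9 were measured, and 6 of these rose, also adjusted over the list alone (camera, adjusted p = 0.0133, and adjusted p = 0.579 with an estimated correlation). This call ended with no filter (0.0824) and with a filter of 10 implied fragments (0.114), over a range of 0.000565 to 0.114. OLIG3 rose from 0.736 ± 0.239 to 10 ± 3.47, MAP2 from 1.35 ± 0.739 to 11.2 ± 2.73 and TUBB3 from 75.4 ± 24.4 to 247.5 ± 40.5. The rise of FABP7 (adjusted p = 0.0215) ended without primed RUES2 replicate 1 (0.0773) or 2 (0.0519) or naive RUES2 replicate 1 (0.0738) or 3 (0.0502). Of 12 primitive endoderm markers 9 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.0133, and adjusted p = 0.598 with an estimated correlation). GATA4 rose from 3.72 ± 0.585 to 9.52 ± 2.72, NID2 from 0.997 ± 0.0576 to 8.76 ± 6.28 and COL4A2 from 25.9 ± 1.94 to 67.6 ± 19.4. FLRT3 (0.97, 0.0276) lost its call without primed RUES2 replicate 1 (0.0625) or 3 (0.0986) or naive RUES2 replicate 1 (0.105) or 3 (0.0633). Of 18 fibroblast markers 11 rose and 2 fell (12 and 2 adjusted over the list alone; adjusted p = 0.00723, and adjusted p = 0.668 with an estimated correlation). DCN rose from 0.0911 ± 0.0618 to 11.1 ± 12.3, and THY1 and S100A4 fell (S100A4 at -1.43, ended without primed RUES2 replicate 1 at 0.0508). Their levels differed widely between replicates. COL3A1 measured 109.6, 85.5 and 445 FPKM and LUM 38.7, 22.6 and 207 FPKM in naive RUES2 replicates 1, 2 and 3. The lists of amnion (3 higher and 1 lower of 7; adjusted p = 0.122), trophectoderm (3 and 2 of 8; 0.838), neural crest (5 and 3 of 11; 0.807) and definitive endoderm markers (3 and 2 of 9; 0.838) were not called, with the same counts when adjusted over the list alone. In them CDX2 (0.305 ± 0.234 to 4.62 ± 2.36), NR2F2 (0.563 ± 0.155 to 2.83 ± 1.33), and POSTN (0.64 ± 0.262 to 4.58 ± 2.31) rose. So did CDH10 (0.156 ± 0.237 to 2.69 ± 0.682), MSX1 (0.538 ± 0.401 to 9.94 ± 4.04), SNAI2 (0.278 ± 0.292 to 6.25 ± 3.36) and TWIST1 (0.435 ± 0.124 to 20.2 ± 2.85). KRT7 (7.53 ± 1.54 to 0.354 ± 0.263), FOXD3 (4.89 ± 1.65 to 0.243 ± 0.0486), HHEX (5.17 ± 2.44 to 0.965 ± 0.252) and TTR (6.18 ± 3.75 to 1.13 ± 0.796) fell. BMP4 (13.7 ± 4.12 and 23 ± 7.97), ID2 (32.7 ± 9.58 and 41.6 ± 10.8), KRT8 (258 ± 87.1 and 404 ± 119), KHDC1L and SLC34A2 did not pass. GATA6 rose (0.93, 0.0439). Its call ended without primed H9 replicate 1 (0.0556), naive H9 replicate 1 (0.059), any primed RUES2 replicate (0.0514 to 0.126) or naive RUES2 replicate 1 (0.162) or 3 (0.0859).

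In the libraries labelled RUES2 limma called 6749 of 14429 genes, 3336 higher and 3413 lower in the naive state, with the libraries that did not match their line label among those compared. Of these 1847 had a difference of at least 1 on the log2 scale. Rescaling each library to a common sum moved the share of higher genes among the calls from 49.4% to 24.2%. It moved the median log2 fold change of all genes from 0.012 to -0.208. Of 25 lists 13 were called by camera, 10 higher and 3 lower, and 0 with an estimated correlation. Another split of these libraries also gave 13 called lists.

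**Figure D2:**
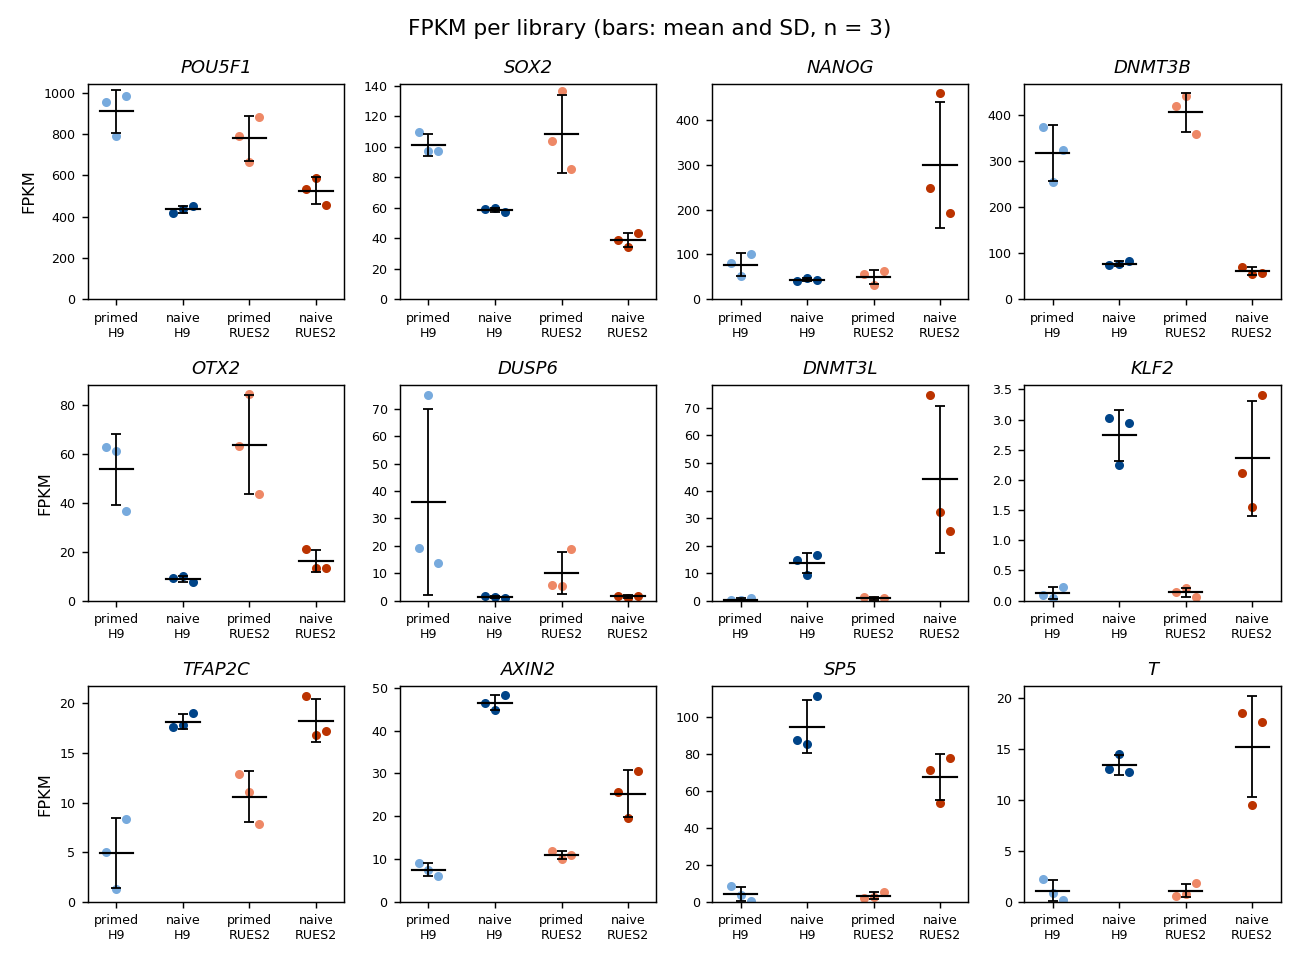
FPKM (vertical axis, linear) of 12 genes in each of the 12 libraries, as points, with the group mean and SD (n = 3) as black bars, for primed H9, naive H9, primed RUES2 and the libraries labelled naive RUES2. NANOG averaged 43.9 FPKM in naive H9 and 299.9 in libraries labelled naive RUES2.

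Averaged over the 2 line labels, the 8 genes with the highest mean fold change were COL3A1, H19, LUM, AQP1, CDX1, HOXB1, SP5 and DNMT3L. COL3A1, a fibrillar collagen gene (chromosome 2, 189839099 to 189877472), rose from 2.51 ± 2.7 to 161 ± 56.5 FPKM in H9 (5.74, adjusted p = 9.61e-05) and to 213 ± 201 in libraries labelled RUES2 (6.37, 4.74e-05). The imprinted long non-coding RNA H19 rose from 5.28 ± 6.36 to 326 ± 185 and from 8.97 ± 6.35 to 222 ± 195, the latter with 444 FPKM in replicate 3 and 145 and 78.4 in replicates 1 and 2. The matrix proteoglycan gene LUM rose from 0.624 ± 0.555 to 43.1 ± 9.79 and from 1.41 ± 0.251 to 89.4 ± 102. The water channel gene AQP1 rose from 0.104 ± 0.0355 to 48 ± 20.4 and from 0.169 ± 0.0323 to 20.5 ± 15.3. The homeobox genes CDX1 (0.236 ± 0.309 to 27.8 ± 3.11 and 0.225 ± 0.221 to 18.4 ± 7.17) and HOXB1 (0.204 ± 0.182 to 31.8 ± 7.65 and 0.252 ± 0.0776 to 9.76 ± 2.68) stood beside SP5 and DNMT3L. Among the genes that fell, GPR176, an orphan receptor gene, went from 59.3 ± 23.4 to 0.32 ± 0.0625 in H9 (-5.44, 2.17e-07) and from 53 ± 3.87 to 1.63 ± 0.366 in libraries labelled RUES2 (-4.37, 8.08e-07). The forebrain transcription factor gene FEZF1 fell from 26.5 ± 11.5 to 0.0831 ± 0.0359 and from 21.1 ± 18.1 to 0.0335 ± 0.0292. The chemerin gene RARRES2 fell from 151 ± 25.5 to 3.58 ± 0.148 and from 139 ± 33.4 to 12.7 ± 3.96. LECT1 fell from 69.8 ± 25.7 to 11.2 ± 2.38 and from 82.6 ± 9.87 to 0.184 ± 0.0651. MAL2, which acts in epithelial transcytosis, fell from 33.3 ± 7.17 to 0.989 ± 0.289 and from 45.2 ± 3.48 to 2.45 ± 0.762. MAP7 (17.6 ± 3.43 to 0.176 ± 0.0413 and 20.7 ± 2.72 to 0.782 ± 0.334), OLFM2 (34.1 ± 15.2 to 1.89 ± 0.514 and 39.3 ± 8.23 to 1.46 ± 0.241) and NLGN4X completed the 8 with the lowest mean fold change.

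For the mean of both state effects limma called 8529 genes, 4214 higher and 4315 lower. Of these 1638 differed by at least 1 on the log2 scale. In both lines 1908 genes were called higher (680 by chance for independent lists) and 2384 lower (816 by chance), and 115 were called in opposite directions (1493.5 by chance). The fold changes of the lines correlated across genes at r = 0.67 and rho = 0.712, and 77.7% had the same sign. In 5455 genes (37.8%) the 3 naive libraries lay apart from the 3 primed ones in the same direction in both lines, where chance gives 0.5%. Rescaling to a common sum moved the share of higher genes among the calls from 49.4% to 27.7%. It moved the median log2 fold change of all genes from 0.009 to -0.162. The 3 libraries that did not match their line label enter this mean.

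**Figure D3:**
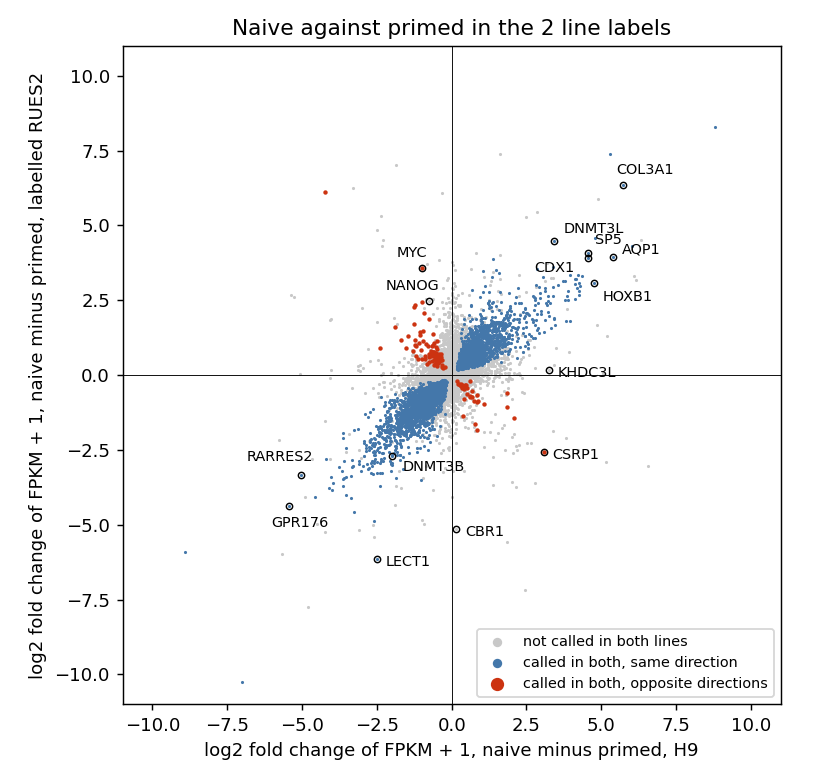
Each point is a gene, placed by its log2 fold change of FPKM + 1 (naive minus primed) in H9 (horizontal) and in libraries labelled RUES2 (vertical), with genes called in both lines in blue (same direction) or red (opposite directions) and all others in grey. COL3A1 lies at 5.74 and 6.37, GPR176 at -5.44 and -4.37, and MYC at -0.99 and 3.58.

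The difference of the state effect between the line labels asked which genes responded differently. MYC, a proto-oncogene transcription factor (chromosome 8, 128748315 to 128753680), measured 31.3 ± 12 and 14.5 ± 0.243 FPKM in primed and naive H9 and 19.5 ± 3.12 and 265 ± 141 in primed RUES2 and the libraries labelled naive RUES2. The difference was 4.57 on the log2 scale (adjusted p = 0.00108). LPPR4 (4.29, 0.000269) reached 21.8 ± 10.2 and SLC6A15, an amino acid transporter gene (3.58, 0.00108), 16.2 ± 5.73 in libraries labelled naive RUES2. DSCR8 (3.77, 0.000187) was listed at 0 in the 6 H9 libraries and measured 14.2 ± 4.48 there, and LOC100130964 (3.63, 0.00529) was listed at 0 in the primed libraries and measured 14.1 ± 10.4. NANOG also differed (3.25, 0.00516), as did MATK (3.31, 0.00438), HLA-DQB1 (3.48, 0.00403) and TWIST1 (2.51, 0.00816, ended with a pseudocount of 0.1 at 0.0795, range 0.000224 to 0.0795). In the opposite direction, the carbonyl reductase gene CBR1 (-5.29, 0.000751) measured 28.4 ± 10.6 and 30.3 ± 6.14 in H9 but 48.8 ± 26.5 and 0.284 ± 0.164 in libraries labelled RUES2. C9orf64 (-3.59, 0.000187) measured 5.27 ± 1.77 and 7.04 ± 0.351 against 9.86 ± 1.77 and 0.178 ± 0.0176. CSRP1 (-5.64, 0.00233) measured 1.62 ± 1.59 and 20.7 ± 11.2 against 16.5 ± 7.39 and 1.86 ± 0.749. The cathepsin gene CTSF (-3.50, 0.000187) measured 0.131 ± 0.127 and 3.83 ± 1.31 against 18.6 ± 2.61 and 6.26 ± 0.985. LECT1 (-3.64), KHDC3L (-3.08), HOXB1 (-1.68, ended with a pseudocount of 0.1 at 0.0976, range 0.0013 to 0.0976), SLC7A11 (-1.58), AXIN2 (-1.38, adjusted p = 0.00816) and ZFP42 (-0.87, 0.014) differed as well, RARRES2 by 1.68.

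Limma called 823 genes for this difference, 544 with a more positive and 279 with a more negative effect in libraries labelled RUES2. Of these 469 differed by at least 1. The share of the former moved from 66.1% to 55.9% with quantile normalization and to 54.7% with sums that left out short RNAs. Camera called 3 lists, WNT targets lower (4 members called and 7 adjusted over the list alone; adjusted p = 0.000402), proliferation lower (0 called, also adjusted over the list alone; 0.0237) and cholesterol synthesis higher (1 called, PMVK, also adjusted over the list alone; 0.0296), each at adjusted p = 0.912 with an estimated correlation. The WNT targets called were AXIN2, NKD1, TNFRSF19 and RNF43. The TNFRSF19 call ended without naive H9 replicate 1 or 2, naive RUES2 replicate 1, primed H9 replicate 1 or primed RUES2 replicate 1 or 2 (0.0523 to 0.0744). That of PMVK was kept only when the library left out was primed H9 replicate 2 or naive RUES2 replicate 2 or 3 (0.0506 to 0.0951 without any other 1). The proliferation call ended without primed H9 replicate 3 (0.143), naive H9 replicate 2 (0.0624) or primed RUES2 replicate 2 (0.0695) and with library weights (0.079), over a range of 0.0013 to 0.143. The cholesterol call ended without primed H9 replicate 2 (0.527), naive H9 replicate 3 (0.0578), primed RUES2 replicate 1 (0.198) or 2 (0.0901) or both primed replicates 2 (0.635), over a range of 1.21e-05 to 0.635. The gene count fell to 379 without naive RUES2 replicate 2, to 391, 426 and 438 without naive H9 replicates 1, 2 and 3, to 407 without primed RUES2 replicate 1 and to 416 without naive RUES2 replicate 1. It fell to 424 with a filter of 5 FPKM and rose to 3529 with library weights. The 3 libraries that did not match their line label enter it.

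The primed groups of the lines were compared as well. CTSF was higher in primed RUES2 (4.11, adjusted p = 4.53e-06), as were LOC100216479 (0.995 ± 0.381 in H9 and 16 ± 4.16 in RUES2; 3.08, 5.46e-05), LOC100505876 (2.3 ± 1.16 and 22.3 ± 4.46; 2.85, 0.000118) and the apolipoprotein gene APOA2 (4.56 ± 3.3 and 41.8 ± 12.3; 3.17, 0.019, ended without primed RUES2 replicate 1 at 0.1). CSRP1 was higher too (2.83, 0.0225), a call that ended without primed H9 replicate 1 (0.0714) or 2 (0.053) or primed RUES2 replicate 1 (0.0914) or 3 (0.0611). SMIM3 was lower in primed RUES2 (28 ± 6.3 and 5.13 ± 0.509; -2.22, 7.85e-05), as was the interferon-induced gene IFITM2 (157 ± 25.6 and 44.8 ± 2.68; -1.77, 7.85e-05). HLA-DQB1 (-2.12, 0.0189), the pseudogene OR7E12P (-1.62, 0.0234) and the stress-responsive gene IER3 (-1.48, 0.025) were lower, with calls that ended without primed RUES2 replicate 1 (0.0959, 0.0765 and 0.1) and, for OR7E12P and IER3, without primed H9 replicate 1 (0.0769 and 0.0814). HLA-DQB1, IFITM2 and OR7E12P have near-identical copies and are uncertain. Limma called 262 genes, 194 higher and 68 lower in RUES2. Of these 102 differed by at least 1. The count was 94 without the libraries labelled naive RUES2, from 44 (without primed RUES2 replicate 1) to 385 (without primed H9 replicate 3) with 1 library left out. It was 2603 with library weights, 170 with the replicate block, 30 in a fit of the 6 libraries alone and 12 in that fit with the block. The share of higher genes moved from 74.1% to 62.8% with quantile normalization.

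Between the naive groups more genes differed. LPPR4 (4.23, adjusted p = 1.32e-05), MYC (3.98, 9.46e-05), DSCR8 (3.88, 4.87e-06), LOC100130964 (3.63, 0.000307) and the tyrosine kinase gene MATK (0.161 ± 0.0687 in H9 and 13.1 ± 7.79 in libraries labelled RUES2; 3.47, 0.000184) were higher in libraries labelled naive RUES2. CBR1 (-4.60, 5.89e-05), the imprinted gene NDN (23.6 ± 0.555 and 0.859 ± 0.0977; -3.72, 0.0024), SMIM3 (31.6 ± 1.51 and 1.54 ± 0.363; -3.69, 1.94e-06), LECT1 (-3.34, 2.98e-05) and KHDC3L (-3.10, 6.96e-06) were lower. Limma called 2289 genes, 1612 higher and 677 lower in libraries labelled naive RUES2. Of these 529 differed by at least 1. Their number fell to 1182, 1269 and 1386 without naive H9 replicates 1, 2 and 3 and to 1346 and 1179 without naive RUES2 replicates 1 and 2, and rose to 6396 with library weights. The 3 libraries that did not match their line label enter this comparison. The share of higher genes among the calls depended on scaling, from 70.4% to 58.4% with median-of-ratios factors, 54.3% with quantile normalization and 44.9% with sums that left out short RNAs.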

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

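The tests for a mislabelled sample, for cells of another line, for cells of another type (in both line labels), for gene length in libraries labelled RUES2 and for short RNAs in libraries labelled RUES2 were chosen only after the results were seen, as were scaling by sums without short RNAs and the runs without the libraries labelled naive RUES2. The genes and lists of the next paragraph stand here because the test of the difference between the line labels called them, and 2 lists that rose in both line labels are weighed after them.

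The state effect differed between the line labels for 823 genes. Differences on the log2 scale, RUES2 minus H9, were 4.57 for MYC, 4.29 for LPPR4, 3.77 for DSCR8, 3.63 for LOC100130964, 3.58 for SLC6A15, 3.48 for HLA-DQB1, 3.31 for MATK, 3.25 for NANOG, 2.51 for TWIST1 (ended with a pseudocount of 0.1 at 0.0795), 1.68 for RARRES2, -0.87 for ZFP42, -1.38 for AXIN2, -1.47 for SMIM3, -1.58 for SLC7A11, -1.60 for LOC100216479, -1.68 for HOXB1 (ended with a pseudocount of 0.1 at 0.0976), -2.48 for LOC100505876, -3.08 for KHDC3L, -3.50 for CTSF, -3.59 for C9orf64, -3.64 for LECT1, -5.29 for CBR1 and -5.64 for CSRP1. SLC34A2 differed by -1.06. The 7 that follow lost their call when some 1 library was left out. IER3 (1.72) ended without primed H9 replicate 1, naive H9 replicate 1 or 3, primed RUES2 replicate 1 or naive RUES2 replicate 1 (adjusted p 0.0533 to 0.0724). GPNMB (1.08) ended without any 1 naive H9 library or primed RUES2 replicate 1 or 2 (0.0504 to 0.0708), and IFITM2 (0.83) without naive H9 replicate 1 or 3, primed RUES2 replicate 1 or naive RUES2 replicate 1 (0.0612 to 0.0702). KHDC1L (-1.48) ended without primed H9 replicate 1 or 2, any 1 primed RUES2 library or naive RUES2 replicate 2 or 3 (0.0564 to 0.0978). The COX7B call (0.46) was kept only when the library left out was naive H9 replicate 3 or naive RUES2 replicate 2 (0.0508 to 0.111 otherwise). That of OLIG3 (-1.21) was kept only for primed H9 replicate 1, primed RUES2 replicate 3 or naive RUES2 replicate 3 (0.0515 to 0.0771 otherwise), and that of TFE3 (-0.66) only for primed H9 replicate 2, primed RUES2 replicate 2 or naive RUES2 replicate 3 (0.0569 to 0.0873 otherwise). Among lists, camera gave adjusted p = 0.000402 for WNT targets, 0.0237 for proliferation and 0.0296 for cholesterol synthesis, each at adjusted p = 0.912 with an estimated correlation, and the latter 2 calls ended without some 1 library, as given in the report.

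A mislabelled or mixed line is 1 candidate explanation for the difference between the line labels: in the check with genotype-dependent genes, 3 libraries did not match the other libraries of their line label, which a sample of another line carrying the label would give. Of 51 genes with at least 2 FPKM restricted to libraries labelled naive RUES2, 41 had a similar ratio of replicate 2 over replicates 1 and 3. Their log2 ratios lay within 0.5 of the median of the 51, 1.09 (2.13-fold), a window that held 2.96% of 11317 genes. A varying share of cells of another line could give this. So could regulation of these genes together, since the window was centred on their own median. Some restricted genes had log2 ratios in the other direction, such as DSCR8 (-0.76), MAGEA3 (-0.33), MAGEA6 (-0.33) and NUPR1 (-1.03), which 1 shared source would not give. Against a mixture with a sizeable share of RUES2 cells, 4 genes at 2 FPKM or more in every other library were at 10% or less of the lowest of these in all 3 (3 genes were in naive H9 by the same bounds), among them CBR1 at 0.395, 0.0958 and 0.36 FPKM (27.1 to 78.3 in primed RUES2), so it stays open only if naive RUES2 cells lack these transcripts. Another line making up these libraries as a whole stays open. A true difference between H9 and RUES2 would not give a mismatch within 1 line label, so it cannot by itself account for the check. In the gene differences neither it nor culture changes acquired by 1 line could be told apart from another line. Neither was tested. Chance can be excluded for the mean effect (1 of 100 splits as large, 8529 genes against at most 1814), and 2 of 100 splits gave a difference as large as the real one (823 against at most 1762), where the larger split exchanged the line labels of all 6 naive libraries and so gave the line difference averaged over both states by construction.

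Of 18 fibroblast markers 11 were higher in naive than in primed libraries in each line label, and both calls of the list ended with an estimated correlation (adjusted p = 0.563 in H9 and 0.668 in RUES2). Short RNAs taking a share of the FPKM sum are argued against as the cause in libraries labelled RUES2, where rescaling moved the median of all genes by -0.07 on the log2 scale and 11 of 11 members stayed called higher, while in H9 it moved all genes up (0.02), so that the 11 of 11 members still called there decide nothing. All 6 low-baseline markers besides COL3A1 were highest in the naive library with the most COL3A1, replicate 3, in each line label. The median was 2.85-fold over the other 2 in RUES2 (36.6% of expression-matched genes highest there) and 1.45-fold in H9 (45%). Members varied together (estimated correlation 0.583), so this cannot tell cells of another type from joint regulation. Not all moved alike: THY1 was lower in naive libraries in both line labels and S100A4 in those labelled RUES2. Mouse feeder transcripts aligned to the human genome were not tested and stay open, as do mesenchymal cells arising in the cultures. Feeder use is not stated for naive cells.

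Of 39 nuclear oxidative phosphorylation genes 17 rose and 1 fell in H9 and 28 rose and 2 fell in libraries labelled RUES2, and both calls of the list ended with an estimated correlation (adjusted p = 0.561 and 0.579). Short RNAs taking a share of the sum are argued against as the whole cause in libraries labelled RUES2, where 24 of 28 members stayed called higher after rescaling (median of the 28 at 0.34 before and 0.27 after), while the 17 of 17 members still called in H9 decide nothing, since rescaling moved all genes up there. Gene length could account for the rise in H9, where 9.29% of 10000 random lists matched on transcript length and expression had a median as high as that of the list (0.17, against 0.06 in the matched lists), with lengths for 32 of 39 members. In libraries labelled RUES2 0.43% of lists had a median as high (0.32 against 0.13). The random lists were drawn gene by gene, while members of the real list varied together (estimated correlation 0.265). Medians of such random lists vary less than those of correlated lists, so this share cannot decide on gene length there. A change of metabolism with the state stays open and was not tested.

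Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split and the highest other gave 6392 and 2 genes for H9 (1 of 10 as large), 6749 and 1 for libraries labelled RUES2 (1 of 10), 262 and 14 for the primed groups (1 of 10) and 2289 and 2 for the naive groups (1 of 10). For called lists they gave 13 and 14 in H9 (2 of 10) and 13 and 13 in RUES2 (2 of 10). For the 3 lists called for the difference between lines chance could not be excluded, since 96 of 100 splits gave as many and the highest other gave 14.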

How the results depend on the processing

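Scaling by sums without short RNAs, the filter on implied fragments and the runs without both primed replicates 2 or without the libraries labelled naive RUES2 were chosen after the data were seen. Of the values of named genes over all settings, 7162 stayed on the same side of the threshold (25 of them, none called, with the other sign), 216 lost the call, 49 gained one and 0 called values turned. Lost calls numbered 155 with 1 library left out, 18 with rescaling to a common sum, 8 without both primed replicates 2, 7 with no filter, 6 with sums that left out short RNAs, 5 each with a pseudocount of 0.1 and quantile normalization, 4 with the replicate block, 3 with a pseudocount of 5, 2 each with median-of-ratios factors and robust variances and 1 with library weights. Calls that held with each library left out but ended otherwise were those of TWIST1 (0.0795) and HOXB1 (0.0976) for the difference with a pseudocount of 0.1, LOX (0.0967) and HHEX (0.124) in H9 with a pseudocount of 5, and, with rescaling to a common sum, NDUFB3 (0.0718) and RRM2 (0.0604) in H9 and TYMS (0.0666), SLC7A11 (0.103) and HSPH1 (0.11) in libraries labelled RUES2. The state counts in H9, in libraries labelled RUES2 and for their mean moved by over 1.5 times only with stricter thresholds: with a difference of at least 1 on the log2 scale to 1687, 1847 and 1638, and at an adjusted p under 0.01 to 4118 in H9. The difference between lines (823) moved to 424 with a filter of 5 FPKM, 3529 with library weights, 469 with at least 1 on the log2 scale, 218 under 0.01, and between 379 (without naive RUES2 replicate 2) and 861 (without primed H9 replicate 2) with 1 library left out, and to 391, 426 and 438 without naive H9 replicates 1, 2 and 3, 407 without primed RUES2 replicate 1 and 416 without naive RUES2 replicate 1. The primed line difference (262) moved to 102 with a filter of 5 FPKM and 102 with at least 1 on the log2 scale, 402 with at least 10 implied fragments, 2603 with library weights, 43 under 0.01, 94 without the libraries labelled naive RUES2, 30 in a fit of the 6 libraries alone, and between 44 (without primed RUES2 replicate 1) and 385 (without primed H9 replicate 3). The naive line difference (2289) moved to 1469 with a filter of 5 FPKM, 1522 with rescaling to a common sum, 6396 with library weights, 529 with at least 1 on the log2 scale, 965 under 0.01, and between 1179 (without naive RUES2 replicate 2) and 2814 (without primed H9 replicate 3), with 1182, 1269 and 1386 without naive H9 replicates 1, 2 and 3 and 1346 without naive RUES2 replicate 1. Filters and stricter thresholds take genes out by design, and for the other changes the cause was not tested. Called lists fell to 0 in H9, 0 in libraries labelled RUES2 and 0 for the difference with an estimated correlation. For the difference (3 lists) they were 5 with no filter, 6 with at least 10 implied fragments, 0 by fry, and between 1 (without primed RUES2 replicate 2) and 5 (without naive RUES2 replicate 3), and the cause was not tested. The correlation of the lines across genes (0.67) was 0.652 with a pseudocount of 0.1 and between 0.645 (without primed H9 replicate 2) and 0.692 (without naive RUES2 replicate 2). With the replicate number as a block the counts were 6289, 6692, 8493, 713, 170 (primed) and 2059 (naive), and 12 for the primed lines in 6 libraries. Libraries with the same number shared little deviation (correlations of -0.054 to 0.136), although in RUES2 each of the 3 numbers correlated best with its own. Depth limits genes of 1 to 2 FPKM, at a median of 47.8 to 112 implied fragments.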

Other observations

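The gene families here, the genes of single libraries, the counts with no filter and the runs without the libraries labelled naive RUES2 were chosen after the values were seen. Ranges give the called genes over the 4 other scalings and then over runs with 1 library left out, and no called member turned with another scaling after the filter.

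Many HOX genes, homeobox genes that pattern the body axis, rose in naive libraries. Of 39 HOX genes listed, 28 passed the filter, 23 of them with every primed library under 1 FPKM, so the filter itself favours genes that rise, and counts are given with no filter. Genes so near 0 in primed libraries can hardly be called lower, with or without the filter. That 0 fell therefore carries no weight. In H9 22 of 38 rose and 0 fell (20 to 23 rose over scalings, 16 to 24 with 1 library left out). In libraries labelled RUES2 31 rose and 0 fell (30 to 33 over scalings, 26 to 33 with 1 library left out). With the filter, HOXB2 rose from 0.398 to 18.5 FPKM in H9 (log2 fold change 3.87, adjusted p = 1.17e-05, limma) and from 0.785 to 11.5 in libraries labelled RUES2 (2.80, 8.76e-05), and HOXA7 from 0.163 to 6.77 and from 0.0513 to 5.39. Without the libraries labelled naive RUES2, 21 of 38 rose in H9. The state effect was more positive in libraries labelled RUES2 for 6 HOX genes and more negative for 2 (6 and 2 with each scaling, 5 to 7 and 2 with 1 library left out). HOXD9, HOXD10 and HOXD11, called more positive with the filter, are among the 51 genes restricted to libraries labelled naive RUES2. For those genes another line was weighed above. In naive H9 they averaged 0.148, 0.137 and 0.197 FPKM and did not pass for the state effect. Of 19 WNT ligand genes, again with no filter, 10 rose and 0 fell in H9 (10 to 12 rose over scalings, 9 to 11 with 1 library left out). Of the 9 past the filter, 4 had every primed library under 1 FPKM, and a fall of such genes can hardly be called. In libraries labelled RUES2 7 rose and 0 fell (7 rose with each scaling, where rescaling to a common sum gave 1 lower, and 6 to 9 with 1 library left out, with at most 1 lower). Examples were WNT8A (0.922 to 21.1 and 0.534 to 11.5) and WNT5B (1.03 to 11.6 and 1.08 to 11.5).

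Most of the epithelial junction genes examined fell and most of the mesenchymal genes rose, counted gene by gene with no list test. Of 20 junction and epithelial genes 17 fell in H9 and 1, DSP, rose (17 fell with each scaling, 16 to 17 with 1 library left out). In libraries labelled RUES2 18 fell and 0 rose (18 fell with each scaling, 16 to 18 with 1 library left out). The E-cadherin gene CDH1 fell from 53.7 ± 22.9 to 3.34 ± 0.878 in H9 (-3.59, adjusted p = 1.01e-05, limma) and from 78.7 ± 6.56 to 10.1 ± 3.39 in libraries labelled RUES2 (-2.88, 3.78e-05). CLDN7 fell from 39.2 to 1.07 and from 50.6 to 6.88, GRHL2 from 5.03 to 0.0683 and from 7.4 to 0.121, and EPCAM from 114 to 43.7 and from 144 to 42.8. Of 8 mesenchymal genes 7 rose and 0 fell in each line label (7 with each scaling, 6 to 7 in H9 and 7 in RUES2 with 1 library left out), with ZEB1 at 0.97 and 1.70, ZEB2 at 1.57 and 1.78 and VIM at 0.96 and 1.82 on the log2 scale. Of the 8 mesenchymal genes 4 in naive H9 and 5 in libraries labelled naive RUES2 were highest in replicate 3, the library with the most COL3A1, with SNAI2, CDH11 and VIM in both, while 2 (CDH2 and ZEB1) were lowest there in naive H9. IGF2 and H19 were highest there in both. SNAI2 measured 15.8, 5.86 and 24.5 FPKM in naive H9 and 5.83, 3.12 and 9.8 in libraries labelled naive RUES2, and IGF2 24.8, 17.2 and 44.3 and 13.1, 9.31 and 44.9. Of 18 HLA genes 14 fell and 0 rose in H9 (12 to 15 fell over scalings, 11 to 16 with 1 library left out) and 12 fell and 1 rose in libraries labelled RUES2 (11 to 12 fell in both kinds of run). HLA genes share reads with near-identical copies and are uncertain. IGF2, an imprinted neighbour of H19, rose from 0.602 to 28.8 ± 14 in H9 (4.21, 0.000195) and from 0.898 to 22.5 ± 19.6 in libraries labelled RUES2 (3.35, 0.000723).

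Single primed libraries stood apart from the other 2 of their group at some genes. Genes with at least 10 FPKM there and at most 20% of that in each of the other 2 numbered 8 in primed H9 replicate 3, 6 in primed H9 replicate 2 and 6 in primed RUES2 replicate 2, and genes lacking there by the same bounds 0, 7 and 2. In primed RUES2 replicate 2 several genes, chosen after their values were seen, lay nearer to the primed H9 mean than to replicates 1 and 3. MEG3, an imprinted long non-coding RNA, measured 0.387 FPKM in it, 45.2 and 33.2 in replicates 1 and 3 and 0.244 on average in primed H9. In the same order IRX2 measured 27.1, 0.59, 0.634 and 13.2, NDN 18.2, 1.51, 2.42 and 14.7, and CHCHD2 239, 35, 33.9 and 211. PTPRD measured 6.82, 0.191, 0.207 and 6.21, and ZNF714 8.16, 0.815, 0.735 and 6.37. UNC5D measured 6.37 in it, was listed at 0 in replicates 1 and 3 and averaged 7.96 in primed H9. In this library PTPRD, ZNF714 and UNC5D lay under the bound of 10 FPKM, so they are not among the genes counted above. Without this library 328 genes differed between the primed groups and 6074 between the states of RUES2 (262 and 6749 with it). Across genes this library correlated at 0.9426 and 0.9414 with primed RUES2 replicates 1 and 3. With primed H9 replicates 1, 2 and 3 it correlated at 0.9266, 0.9455 and 0.9302. Primed RUES2 replicate 3 correlated with primed H9 replicate 2 at 0.9445, so such a value is not particular to replicate 2. Deviations from the group means correlated at 0.136 between both primed replicates 2, the highest value among the pairs compared. The check of line identity does not settle whether primed RUES2 replicate 2 carries the right label.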
